A study of Arabidopsis thaliana with 6 samples.

How the data were processed

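RNA abundance was measured in unopened flower buds of Arabidopsis thaliana, in wild type plants of the Columbia accession and in plants carrying a mutation in DDM1, a chromatin remodelling protein needed for DNA methylation and for the silencing of transposable elements. The labels give 3 biological replicates for each of the 2 genotypes, 6 arrays in all, and place the ddm1 plants in inbred generation 6. Plants grew on soil at 23 °C with 18 hours of light a day, per the labels' protocols. Total RNA was amplified, labelled with biotin and hybridised to a 1-colour oligonucleotide array, per the labels' protocols.

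The authors computed expression values with GCRMA, per the submitters' processing notes, and its version is not given in the sources used here. The deposited values are on a log2 scale, centred for each probe set on a baseline. The base of the logarithm was inferred from GCRMA and from the range of the values, from -10.0 to 8.57. The baseline is not the median of these 6 arrays. At most 4 of the 6 values of a probe set lie above 0 and at most 4 below, 83.7% of the probe sets hold an exact 0 in at least 1 array, and the median over the 6 arrays is 0 within 1e-06 in 12.5%. These limits would fit a median over 9 arrays, and the baseline samples are not given in the sources used here. Centring keeps the differences between arrays and removes the level of each probe set. Whether a probe set lay above background in a group is therefore unknown. GCRMA compresses dim signals, so a difference against a group near background may understate the change. The array medians of the deposited values were 0, 0 and 0.00675 in wild type, and -0.00642, 0 and 0.0175 in ddm1.

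The table held 22810 probe sets. After 64 control probe sets were left out, 22746 were tested. The annotation of the array named 1 gene for 13513 of them and several genes for 503, and 8730 were unnamed here. No gene was named from a probe set that lists several. Of the single-gene probe sets, 13436 were matched by gene number to the RefSeq gene table of assembly TAIR10.1, which gave symbols, gene types and the order of neighbouring loci, and 77 were not matched. No coordinates are printed, because the build behind the array is not given in the sources used here.

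The design called for a count of transposable element genes, and the tables used here hold no such gene type. The RefSeq type pseudogene, which in Arabidopsis takes in annotated transposable element genes together with other pseudogenes, stood in for it. It covers 923 probe sets, called pseudogene-type loci in the text, and element families were not analysed here. A further 66 probe sets belong to the separate type transcribed pseudogene and were counted among the other genes.

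Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values of all 6 arrays with genotype as the only term. P-values are two-sided and adjusted by Benjamini-Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. A second count required a change of at least 2-fold. Pseudogene-type and other single-gene probe sets were compared with Fisher's exact test, which treats probe sets as independent although all were read on the same 6 arrays. The same test was used for genes lying in windows of 25 consecutive loci of which at least 50% are pseudogene-type, taken as pericentromeric and similar regions. Gene lists with at least 3 probe sets were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 8 lists (7 fixed lists and the pseudogene-type loci). Permutations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

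Before the data were examined, 21 gene lists with 311 genes were fixed, along with the tests, the alternatives and the rule for naming genes. The annotation names 46 of the 311 genes by a probe set of their own. Measured were 10 of 19 pollen, 3 of 21 tapetum and pollen wall, 5 of 16 meiosis and 3 of 26 photosynthesis genes. For DNA methylation and heterochromatin machinery it was 3 of 27, for cold, drought and abscisic acid response 3 of 14, and for reference genes 3 of 11. Counts and tests of a list cover its measured genes only. DDM1 itself, UBP1B, SDC, FWA and SNC1 were not analysed here, so the mutated gene gives no check of the labels. No gene of the lists for RNA-directed DNA methylation and seed storage was analysed here either. The rule named DDM1 first. It then took, among single genes called at least 2-fold with the groups fully apart, the 10 largest rises and 10 largest falls outside the pseudogene-type loci, and the 6 largest rises and up to 3 largest falls within them. It added up to 4 members of each list with the lowest adjusted p, and QQS. For a gene with several probe sets the rule takes the one with the highest mean, and because the centred values hold no level, all 3 probe sets of DME, the gene concerned, are given.

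The fit was tested on simulated data with 22746 probe sets and 200 changed ones. It recovered 77% of 100 changes of 2-fold and 96% of 100 changes of 4-fold, and 3.35% of its calls were false. In 20 simulated sets with no change it called 0. The simulated noise was normal and independent between probe sets, with the same SD in both genotypes. Correlation among probe sets and the wider spread in ddm1 were not simulated, so error rates in the real comparison may differ. The number of arrays limits the precision, and no array signal or depth measure was used here. The 3 arrays of a genotype differed from each other with a standard deviation (SD) over probe sets of 0.177 to 0.194 in wild type and 0.243 to 0.300 in ddm1, so no array was a copy of another.

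Alternatives covered the variance model, a replicate block, array weights, leaving out each array, a test against a 1.5-fold change, the correlation used by camera, fry, and windows of 15 and 51 loci. Further alternatives were chosen after seeing the data: centring each array on its median, leaving out the 25% of probe sets with the smallest residual SD, and using only probe sets with the plain suffix _at. The suffixes _s_at and _x_at mark probe sets whose probes match several transcripts.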

Results

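The expression data cover 6 arrays of unopened flower buds, 3 from wild type plants and 3 from ddm1 mutants, which the series describes as having high transposable element activity. Genotype was the main division among the arrays. The first principal component held 88.9% of the variance and parted the genotypes, and the second held 4.73% and set ddm1 replicate 1 against ddm1 replicate 3. The median SD of a probe set was 0.0636 on the log2 scale in wild type and 0.0770 in ddm1. Values below are log2 differences of ddm1 from wild type with the standard error (SE) of the limma fit, n = 3 arrays per genotype, and adjusted p-values are limma's with Benjamini-Hochberg adjustment.

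The comparison of ddm1 with wild type asks which transcripts differ in buds between the genotypes. The labels give an inbred generation for every ddm1 array and none for the wild type arrays. Effects of losing DDM1 and of the inbreeding history of the ddm1 plants therefore cannot be told apart here. The largest changes were rises at pseudogene-type loci, the class that holds the transposable element genes, and the 3 deepest falls called at single genes were at protein-coding loci, among them VEX1 (SWEET5), a sugar transporter gene of the pollen vegetative cell. Of 923 pseudogene-type probe sets, 227 were higher in ddm1 and 3 were lower, or 248 and 4 when adjusted over the list alone. Of 12443 protein-coding probe sets, 277 were higher and 686 were lower. Over all 22746 probe sets, 795 were higher and 1291 lower in ddm1, and 379 and 391 of these changed at least 2-fold. The median difference over all probe sets was 0.00445. Leaving out wild type replicate 1, 2 or 3 lowered the counts of higher and lower probe sets to 432 and 629, 527 and 733, or 510 and 775.

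The rises at pseudogene-type loci were large as well as frequent. In this class 212 probe sets rose at least 2-fold, with a median log2 difference of 4.79 among them, and 127 rose more than 16-fold. The odds of being called higher were 14.3 times those of other single-gene probe sets (95% confidence interval 11.75 to 17.38, Fisher's exact test, two-sided, p = 5.36e-134), and 42.5 times for a rise of at least 2-fold (32.6 to 55.9). The ratio of 14.3 was 26.2 without wild type replicate 1, 34.5 without variance moderation, 5.29 with array weights and 9.49 with plain _at probe sets. Fisher's test treats probe sets as independent, so a correlation among them makes its intervals too narrow and its p-values too small. The camera test over the whole class gave an adjusted p of 1.24e-31, and the adjusted p = 0.203 with the correlation estimated at 0.350. The biggest increases were at AT2G12300 (12.15 ± 0.10 SE), AT2G12240 (11.995 ± 0.14), AT2G10640 (11.81 ± 0.22), AT3G30396 (11.41 ± 0.03), AT1G33130 (11.22 ± 0.05) and AT2G13160 (10.82 ± 0.14). All 6 were read by _x_at probe sets, so each value may combine transcripts of several related loci. The share that rose at least 2-fold was 14.99% of 734 plain _at probe sets, 45.0% of 111 _s_at and 66.7% of 78 _x_at probe sets. For protein-coding loci it was 0.615% of 12358 plain _at probe sets. The only pseudogene-type locus that fell at least 2-fold was AT4G16870, at -3.36 ± 0.47 on the log2 scale (adjusted p = 0.0141), and this call was lost without wild type replicate 1 (adjusted p = 0.0595) or replicate 2 (0.0536) and without variance moderation (0.0718).

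**Figure D1:**
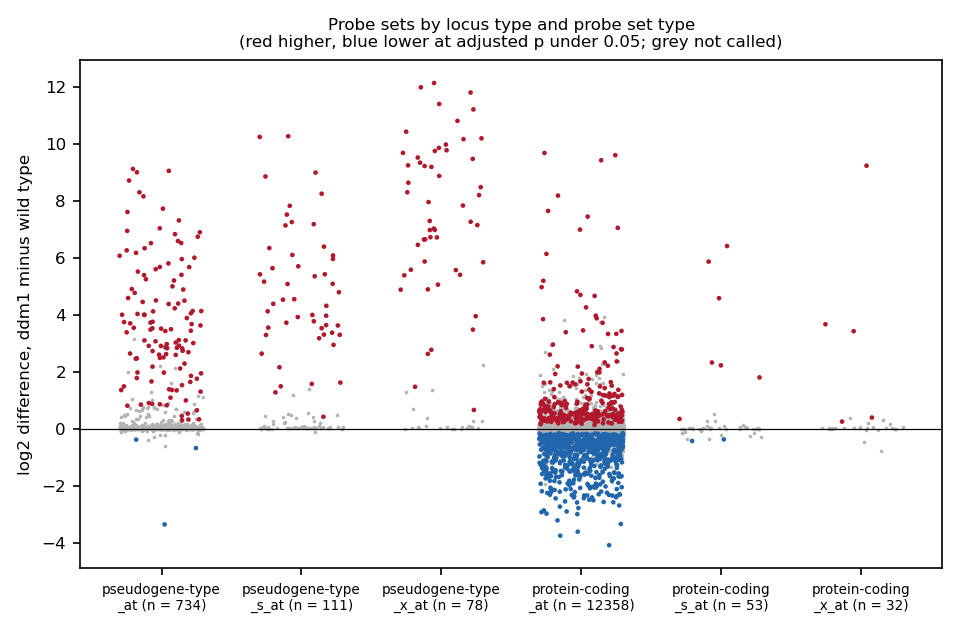
Log2 difference between ddm1 and wild type (vertical axis) of each probe set, by locus type and probe set type (horizontal axis); red points were called higher, blue points lower and grey points neither. Pseudogene-type loci have 227 red and 3 blue points, and protein-coding loci 277 red and 686 blue points.

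Outside the pseudogene-type loci, 9 of the 10 biggest rises belonged to loci typed as protein-coding. They ran from AT4G29200 (6.996 ± 0.06 SE) through AT2G15560 (7.06 ± 0.21), AT5G03090 (7.45 ± 0.10), AT5G01080 (7.65 ± 0.04), AT5G41660 (8.19 ± 0.03), AT1G59930 (9.24 ± 0.14), AT5G26270 (9.43 ± 0.10) and AT1G36240 (9.61 ± 0.13) to AT1G58025 (9.69 ± 0.03). The tenth, AT2G12050, is a transcribed pseudogene and rose by 6.79 ± 0.03. AT1G59930 was read by an _x_at and AT2G12050 by an _s_at probe set, so these values too may combine several loci. Adjusted p-values of these 10 lay at or under 2.96e-05. The wild type arrays were nearly flat at AT1G58025, AT5G26270, AT5G41660, AT4G29200, AT5G01080, AT2G12050 and the pseudogene-type AT3G30396 (SD 0.00589 to 0.0399). Wild type may lie near background there, in which case the sizes of these rises may be understated, and their order is open. A small SD alone does not settle this, since CHX19, a gene that fell in ddm1, had a wild type SD of 0.0304. Rises at probe sets that were less flat in wild type may be understated too.

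Of the 12 genes in the list of genes silenced by DNA methylation, only 2 were measured. Both rose, on the list's own adjustment and over all probe sets. QQS, a starch-related gene known only from Arabidopsis, rose 36.8-fold (5.20 ± 0.22 SE, adjusted p = 0.000141). MPC, an imprinted gene, rose 1.55-fold (0.63 ± 0.12, adjusted p = 0.0358), and its call was lost when each array was centred on its median (adjusted p = 0.0512), in 4 of the 6 fits that left out an array, without variance moderation (0.122) and with a trended, robust variance model (0.0577). The list is too short for a set test.

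**Figure D2:**
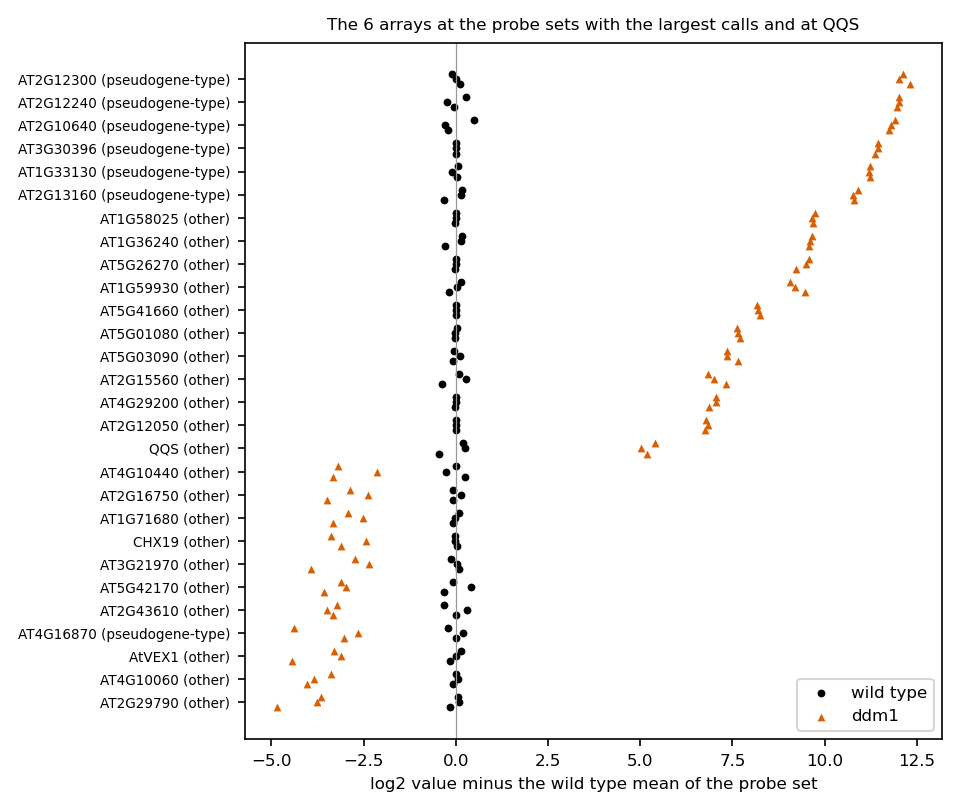
Log2 values of the 6 arrays minus the wild type mean (horizontal axis) at the probe sets with the largest rises and falls and at QQS (vertical axis); circles are wild type arrays and triangles ddm1 arrays. The mean of the ddm1 arrays lies 12.15 above wild type at AT2G12300 and at -4.09 at AT2G29790; the genes of largest rise and fall were picked among those whose groups do not overlap.

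The deepest falls outside the pseudogene-type loci were smaller than the rises. AT2G29790 fell 17.0-fold (-4.09 ± 0.34 SE), AT4G10060 13.5-fold (-3.76 ± 0.17), VEX1 12.2-fold (-3.61 ± 0.36), AT2G43610 10.1-fold (-3.34 ± 0.17) and AT5G42170 9.31-fold (-3.22 ± 0.24). AT3G21970 (-3.00 ± 0.41), the cation/proton exchanger gene CHX19 (-2.98 ± 0.25), AT1G71680 (-2.93 ± 0.21), AT2G16750 (-2.90 ± 0.29) and AT4G10440 (-2.88 ± 0.35) followed. Adjusted p-values of these 10 lay at or under 0.0133. The call of AT3G21970 was lost without wild type replicate 1 (adjusted p = 0.0585) or replicate 2 (0.0504), and those of AT3G21970 and AT4G10440 without variance moderation (0.0691 and 0.0549).

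Some genes of the pollen and tapetum lists fell, and others were not called. The 10 measured genes of the pollen list, out of 19, had a median log2 difference of -0.69 (camera adjusted p = 0.000147, and adjusted p = 0.173 with an estimated correlation). Of these 10, 5 fell and 0 rose, both over all probe sets and adjusted over the list alone. Besides VEX1 these were the pollen allergen-like gene AT5G45880 (-1.93 ± 0.11 SE), the reproductive actin ACT12 (-1.78 ± 0.09) and the pollen MADS-box genes AGL30 (-0.81 ± 0.12) and AGL66 (-0.65 ± 0.03). Members that were not called were AGL104 (-0.72 ± 0.27), AGL65 (-0.10 ± 0.06), ACT11 (0.03 ± 0.13) and the pollen tube receptor kinases ANX1 (0.01 ± 0.03) and ANX2 (-0.01 ± 0.05). With wild type SDs of 0.0136 and 0.0120, ANX1 and ANX2 may lie near background, where a change would not show. In the list for the tapetum, the nursing layer of the anther, and the pollen wall, 3 of 21 genes were measured. Their median was -1.08 (camera adjusted p = 0.00139, and adjusted p = 0.136 with an estimated correlation). Over all probe sets 2 of the 3 fell, and adjusted over the list alone 3 of 3 fell. These were the tapetal regulator AMS (-1.23 ± 0.08), the tapetal gene A9 (-1.08 ± 0.10) and, on the list's own adjustment, the sporogenesis regulator SPL (-0.82 ± 0.26). Of the 5 meiosis genes 0 were called by limma on either adjustment and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.487), with ZYP1B at -0.19 ± 0.09, SPO11-1 at -0.07 ± 0.07, SDS at -0.05 ± 0.06 and MER3 at 0.01 ± 0.03.

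Alongside these falls, of 3 photosynthesis genes, markers of green tissue, 1 rose over all probe sets and 3 adjusted over the list alone (median 0.35, camera adjusted p = 0.00342, and adjusted p = 0.136 with an estimated correlation). The antenna protein genes LHCB4.2 and LHCB4.1 differed by 0.38 ± 0.05 SE and 0.35 ± 0.09, and RCA, encoding Rubisco activase, by 0.20 ± 0.05. LHCB4.2, the member called over all probe sets, lost its call without wild type replicate 1, wild type replicate 2 or ddm1 replicate 2 (adjusted p = 0.0576, 0.0551 and 0.0509) and without variance moderation (0.0575). Of the 3 reference genes 0 were called by limma over all probe sets, and 1 was lower at an unadjusted p under 0.05 and adjusted over the list alone, UBC21 at -0.17 ± 0.05 (PEX4 in RefSeq), beside TIP41 at -0.09 ± 0.08 and SAND at 0.05 ± 0.07 (camera adjusted p = 0.479).

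**Figure D3:**
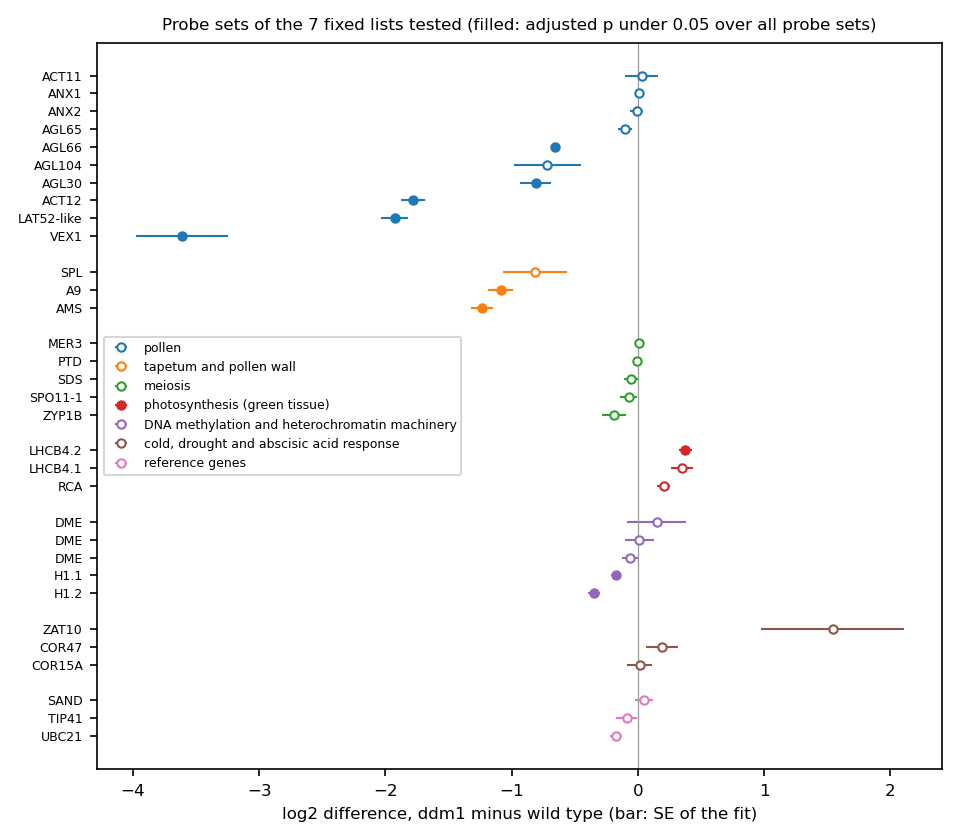
Log2 difference between ddm1 and wild type (horizontal axis, bars are the SE of the fit) for each probe set of the 7 fixed lists tested (vertical axis, coloured by list); filled points were called over all probe sets. VEX1 lies farthest below 0, at -3.61, and the 5 meiosis genes lie between -0.19 and 0.01.

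In the list of DNA methylation and heterochromatin machinery, 2 of 5 probe sets fell over all probe sets and over the list alone, both of linker histone genes, H1.2 (-0.35 ± 0.05 SE, adjusted p = 0.0149) and H1.1 (-0.18 ± 0.04, adjusted p = 0.0492). The camera test found no shift of the list (adjusted p = 0.226, and 0.351 with an estimated correlation), whereas fry for changes in either direction gave an adjusted p of 0.00967. Both calls were lost without variance moderation (adjusted p = 0.0973 for H1.1 and 0.0574 for H1.2). The H1.1 call was also lost in every fit that left out an array, and that of H1.2 without wild type replicate 1, wild type replicate 3 or ddm1 replicate 2 (adjusted p = 0.0638, 0.0589 and 0.0528). The 3 probe sets of the DNA demethylase gene DME gave -0.06 ± 0.07, 0.01 ± 0.11 and 0.15 ± 0.23 and were not called.

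In the list for cold, drought and abscisic acid response 0 of 3 genes were called by limma on either adjustment and 1, STZ, at an unadjusted p under 0.05 (camera adjusted p = 0.226). The zinc finger gene STZ (ZAT10) stood at 1.54 ± 0.56 SE with an SD of 1.103 among the ddm1 arrays, COR47 at 0.19 ± 0.13 and COR15A at 0.01 ± 0.10. Without ddm1 replicate 3 this list passed the camera test (adjusted p = 0.0340). Lists with 1 or 2 measured probe sets were not tested as sets, and apart from the genes silenced by DNA methylation none of their members was called over all probe sets, though UBP1C and SPT had an unadjusted p under 0.05. Those members were AGO7 (0.28 ± 0.12) and SE (-0.13 ± 0.10) of the post-transcriptional small RNA pathway, UBP1C (-0.15 ± 0.04), SAG101 (0.66 ± 0.29) and PDF1.2 (0.09 ± 0.07) of the immune response, and HSP17.6C (0.14 ± 0.11) and HSP22.0 (0.03 ± 0.03) of heat shock. The floral and other lists gave UFO (0.00 ± 0.03), SPT (0.29 ± 0.10), INO (-0.08 ± 0.08), AGL24 (0.41 ± 0.28), GI (0.05 ± 0.05), the DNA ligase gene LIG4 (0.05 ± 0.06) and the replication gene MCM7 (0.05 ± 0.07). UBP1C, the 1 measured member of the UBP1 RNA-binding protein list, was lower when adjusted over the list alone, which for 1 probe set is its unadjusted p of 0.0121.

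The last comparison asks whether changed genes outside the pseudogene-type class lay among loci of that class. Inside windows rich in pseudogene-type loci 9 of 193 probe sets were higher in ddm1 (4.66%) and 8 were lower, against 266 of 12217 (2.18%) higher and 677 lower elsewhere. The odds ratio for a higher call was 2.197 (95% interval 0.978 to 4.33, Fisher's exact test, two-sided, p = 0.0409), and for a lower call 0.737 (p = 0.524). For rises of at least 2-fold, 6 of 193 inside compared with 80 of 12217 outside (odds ratio 4.87, interval 1.71 to 11.3, Fisher's exact p = 0.0022). This 2-fold result rests on 6 probe sets inside the windows and takes in probe sets of all suffixes. None of the alternatives was run for it, so whether it would hold under them is unknown. The result for all higher calls is borderline, its interval including 1, and by the same exact test it was lost without wild type replicate 3 (odds ratio 1.99, p = 0.117), with array weights (1.23, p = 0.414), with plain _at probe sets (1.61, p = 0.285) and with windows of 51 loci (1.87, p = 0.0877).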

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

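No result turned direction past a threshold under any alternative run, and for 65 named genes 781 of 828 values kept their side of the threshold, 38 lost a call and 9 gained one. Planned quantile normalization, centring on bright probe sets, a filter on mean level and a floor were not run, because the deposited values carry no level, and replacements were chosen after seeing the data. Signal over background is unknown for the same reason.

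Without variance moderation, 373 probe sets were higher and 429 lower (222 lower at least 2-fold), with 1 lower pseudogene-type probe set. With array weights, 2185 were higher and 3597 lower, with 6 lower pseudogene-type probe sets, a window odds ratio of 1.23, and an adjusted p of 0.0305 for the DNA methylation list. That estimation stopped with a convergence warning and gave ddm1 replicate 2 a weight of 5.59. Against a 1.5-fold change, 282 were higher and 213 lower. Restricted to plain _at probe sets, an alternative chosen after seeing the data, 250 rose at least 2-fold, 123 pseudogene-type probe sets were higher and the window odds ratio was 1.61, fewer probe sets being tested. Windows of 51 loci gave 1.87. An estimated correlation ended the camera calls of the pollen (adjusted p = 0.173), tapetum (0.136), photosynthesis (0.136) and pseudogene-type (0.203) lists. Directional fry, which does not compare a list with other genes, kept all 4 (adjusted p = 0.000691, 0.000598, 0.0011 and 0.000312). Fry for either direction gave 0.00967 for the DNA methylation list. Where no reason is named, the cause was not tested.

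Leaving out 1 array gave 432 to 788 higher and 629 to 1011 lower probe sets, 1 to 3 lower pseudogene-type probe sets, odds ratios of 13.2 to 26.2 for pseudogene-type loci and of 1.99 to 4.17 for the windows, and adjusted p-values of 0.0340 to 0.490 for the cold list.

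Whether the replicate numbers pair the arrays is open. Same-numbered arrays correlated in their deviations at 0.0752, 0.0900 and 0.0159 for replicates 1, 2 and 3, and differently numbered pairs from -0.0907 to 0.0229. Replicates 1 and 2 thus lay above every differently numbered pair, and replicate 3 lay within their range. The wild type array correlated best with the ddm1 array of its own number in 2 of 3 cases. With a replicate block 433 probe sets were higher and 553 lower (226 lower at least 2-fold), 864 of these 986 being among the 2086 called without it, and the odds ratio for pseudogene-type loci was 27.2. The calls of AT3G21970, AT4G10440, H1.1, H1.2, MPC and LHCB4.2 were not made with it (adjusted p = 0.0675, 0.0723, 0.0616, 0.0539, 0.0934 and 0.0896).

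The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 2086 called probe sets, 770 at least 2-fold, 230 pseudogene-type, 4 lists and 9 higher in the windows. The highest of the other splits gave 0, 0, 0, 3 and 0. Most of the other splits called at least 1 list, although they mix the genotypes. Camera's list calls at the preset correlation are therefore not particular to the real split.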

Other observations

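The tests of explanations in this part, and the choice of the genes it names, were made after the values had been seen. Among protein-coding genes with a RefSeq symbol, 35 fell and 10 rose at least 2-fold in ddm1. The falls included genes of the cytoskeleton, namely the myosins XIE (-2.15 ± 0.14 SE on the log2 scale) and XIC (-1.68 ± 0.09), and the actin-binding protein genes NET2D (-1.24 ± 0.17) and PLIM2b (-1.03 ± 0.14). They also included the sugar transporter genes SWEET3 (-1.44), SWEET7 (-1.36) and SWEET15 (SAG29, -1.18), and the dehydrin and late embryogenesis genes LEA (-1.93), LTI30 (-1.75) and LEA4-5 (-1.02). SWEET11, of the same transporter family, rose by 1.22, next to the thionin gene THI2.2 (2.11), the subtilase gene SBT5.2 (1.98) and the metallothionein gene MT1C (1.37). No enrichment of these groups was tested.

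A set of genes varied widely among the ddm1 arrays. Of the single-gene probe sets, 95 had an SD over 0.75 in ddm1 and 16 in wild type. Among the 95, ddm1 replicate 3 was the lowest of its group in 57 and replicate 1 the highest in 57. The chitinase gene CHI stood 6.09, 4.93 and 0.49 above the wild type mean in ddm1 replicates 1, 2 and 3, on the log2 scale. The values were 4.08, 3.87 and 0.88 for the calmodulin-like gene CML41, 2.67, 1.49 and 0.51 for the transcription factor gene WRKY53, and 2.70, 1.42 and 0.51 for STZ. None of these 4 was called (adjusted p of 0.203, 0.123, 0.168 and 0.186 from limma). The 12 Bacillus subtilis spike control probe sets averaged -0.54 in wild type replicate 3, and between -0.05 and 0.03 in the other arrays.

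Of the 923 probe sets of pseudogene-type loci 227 were called higher in ddm1 and 693 were not called, and the class's camera call was lost with an estimated correlation (adjusted p = 0.203). Sharing of probes as marked by the suffixes would give no excess among plain _at probe sets. There the odds of a rise of at least 2-fold were 28.5 times those of protein-coding loci (95% interval 20.8 to 39.1, probe sets taken as independent). This argues against such marked sharing as the whole cause, while sharing that the plain suffix does not mark was not tested. Array scaling would move protein-coding probe sets too, and their median difference was 0.00183. The array medians of the deposited values all lay near 0, which held this median near 0 in advance. The value shows only that no shift common to all probe sets remained. A loss of late pollen cells that raised all other transcripts alike would raise photosynthesis genes and pseudogene-type loci by the same amount. Array medians near 0 would take such a common rise out of both, so the photosynthesis median alone cannot test it. That median was 0.352 (SD 0.0935 over 3 of 26 genes), against 4.79 among the 212 pseudogene-type rises of at least 2-fold. The gap shows only that rises of at least 2-fold went beyond what these 3 genes shared. The 15 called rises under 2-fold stay open. No biological explanation, release of silencing in ddm1 included, was tested, and how many loci stand behind each _x_at value stays open.

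In ddm1, 5 of 10 pollen and 2 of 3 tapetum probe sets were called lower, and both lists' camera calls were lost with an estimated correlation (adjusted p = 0.173 and 0.136). Array scaling would lower reference genes, and the lowest of these stood at -0.17 (UBC21, lower on the list's own adjustment). Array medians near 0 kept a shift common to all probe sets small in advance. The value shows only that the 3 measured reference genes did not share falls of the size seen in the pollen and tapetum lists. Fewer anthers of every stage would lower meiosis genes too, whose median was -0.0527, but only 1 of the 5 meiosis probe sets varied by an SD over 0.05 in both groups, and since levels are lost the rest may lie near background. The same 1 usable meiosis probe set leaves younger buds in the ddm1 collections open. A smaller share of anther tissue, younger buds and lower transcription within anthers cannot be told apart here.

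Lower genes next to each other on the chromosomes were seen in 5 runs of at least 3 measured loci, such as AT3G28780 to AT3G28840 (4 loci, -2.32 to -2.57) and AT1G23560 to AT1G23590 (4 loci, -1.03 to -1.55). In the order of TAIR10.1, 45 adjacent measured pairs were both lower among 12294 loci outside the pseudogene type. Placing the 677 lower calls at random 10000 times gave 37.2 such pairs on average and at most 60 (one-sided permutation p = 0.103). The number of pairs therefore lies within the range of chance placement. The number and length of the runs were not tested.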
